A study of Homo sapiens with 18 samples.

How the data were processed

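Transcription starts were measured by cap analysis of gene expression (CAGE), which sequences short tags from the capped 5′ ends of RNA, so that each tag marks a start site and the number of tags measures how much RNA starts there. The 18 libraries came from total RNA, extracted with a Qiagen RNeasy kit and prepared by a published CAGE protocol, per the labels. They cover 2 human acute myeloid leukaemia cell lines, labelled AML2 and AML3 and named OCI-AML2 and OCI-AML3 in the count tables, each with vehicle (DMSO), JQ1 or OTX015 and 3 libraries per group. As background, OCI-AML3 is the standard line with a mutated NPM1 gene, whose protein is displaced to the cytoplasm (NPM1c), and OCI-AML2 lacks that mutation; the labels themselves give no genotype. JQ1 and OTX015 (birabresib) are related thienotriazolodiazepines that occupy the bromodomains of the BET proteins, including BRD2 and BRD3. Their side chains end in a tert-butyl ester in JQ1 and in a hydroxyphenyl amide in OTX015. Doses and treatment times are not given in the labels.

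The deposited tables hold counts, whole numbers of tags that were not normalized, for 14079 gene symbols, 42133 promoters and 3863 enhancers in each library. Every promoter, enhancer and gene listed has at least 3 tags over the 18 libraries. Per the submitters' processing notes, STAR and the hg38 build were used. Their versions, the definition of the promoters and enhancers, any removal of duplicate reads and the counting tool are not given in the sources used here. Because only capped ends were counted, the tags of a gene need no correction for its length. Tags of near-identical gene copies, such as histone, ribosomal protein and metallothionein genes, can be split between copies by the alignment, and the values of such genes are uncertain. Of the gene symbols, 12689 are current, 982 are older symbols and 13585 occur in GENCODE release 29. Gene symbols are printed as the table gives them, so that histone genes carry older names.

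Coordinates were checked before use. Of the promoters, 41307 have names that carry hg19 coordinates, of which 8.05% lay within 500 bases of a GRCh38 transcript start, and 826 carry hg38 coordinates, of which 78.6% did. Of the enhancers, 674 are named in hg19 and 3189 carry no build. The latter were read as hg38, because 37.4% of them lay within 2000 bases of a GRCh38 transcript start against 22.3% after a shift by 50000 bases. Coordinates are given in the build of each name, never converted, and as the tables write them, with the base convention not stated. Genes and enhancers in hg38 were placed with GENCODE release 29, and sites in hg19 were not annotated here. A promoter was matched to a gene only where both had the same counts in all 18 libraries with at least 50 tags, which held for 3035 promoters.

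Differences were tested with edgeR 4.0.16 in R 4.3.3. Negative binomial quasi-likelihood models with 1 mean per group were fitted to all 18 libraries together (12 residual degrees of freedom), with TMM normalization and the filterByExpr filter over the 6 groups. This left 10031 genes and 12867 promoters. Enhancers with at least 3 tags in at least 3 libraries were tested (849), using library sizes and TMM factors of the promoter table so that a change of all enhancers stays visible. The comparisons were AML3 against AML2 with vehicle, each compound against vehicle in each line, OTX015 against JQ1 in each line, and the difference of each compound's effect between the lines (an interaction). A gene, promoter or enhancer was said to rise or fall where the Benjamini-Hochberg adjusted p was under 0.05. Tests were two-sided. Levels are CPM, tag counts scaled to the size of the library multiplied by its TMM factor. They are given as mean ± SD with n = 3 libraries, and changes are log2 fold changes with their standard errors (SE). For genes the TMM factors ran from 0.7689 (AML2 vehicle replicate 1) to 1.5538 (AML3 OTX015 replicate 3). Against a group with 0 tags, a fold change is a lower bound computed from a floor of 3 tags over the group. Against 1 to 3 tags, it is a ratio with a 95% counting interval. Such intervals and floors cover counting error only.

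Sets of genes were tested with camera in limma 3.58.1 with a preset correlation of 0.01, adjusted over the 21 lists tested in each comparison, and again with a correlation estimated from the libraries. The 23 lists, the comparisons, the tests, most alternatives and the rule for naming genes were fixed before the data were examined. That rule took, for the line and the 4 drug comparisons, the 10 largest rises and falls among genes that passed the test, averaged at least 10 CPM and did not overlap between the 3 and 3 libraries. It took 5 each way for OTX015 against JQ1 and for the interactions, and up to 4 members with the smallest adjusted p per list and comparison. It also took MYC, HEXIM1, SERPINI1, BCL2, CDK6, MYB, HOXA9, MEIS1, NPM1, BRD2, BRD3, CD14, ITGAM and MPO, and 1 more that is not reported here. CD14 and ITGAM were not among the genes tested, and MPO was not analysed here. For promoters it took the 3 largest rises and falls by the same rule, and for enhancers the 3 smallest adjusted p each way. Of the 243 genes it gave, those whose values or calls changed most on leaving out a library were mostly not described. The share of enhancer tags per library was compared with exact permutation tests of 3 against 3 libraries, for which the smallest possible p is 0.1, with Wilson 95% intervals for single libraries. Proximity of enhancers and promoters was tested with Fisher's exact test. These steps used Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1, and figures used matplotlib 3.10.9.

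Nothing in the labels says that replicates were separate cultures, so p-values measure only the spread between these samples, which may be technical. No 2 libraries of a group agreed within sampling noise (chi-square per degree of freedom 2.08 to 13.9). The libraries held 303883 to 2163106 gene tags, and the median biological coefficient of variation was 17.1% for genes, 18.4% for promoters and 27.2% for enhancers. On counts simulated from these libraries, with 200 genes changed, the comparison of JQ1 with vehicle in AML3 recovered 37.4% of 2-fold and 88.8% of 4-fold changes among 9684 genes, and 4.62% of its calls were false. The simulated JQ1 interaction recovered 4.08% and 60.8% among 9738 genes, with 7.35% of calls false, and the simulated comparison of OTX015 with JQ1 in AML3 recovered 25.3% and 78.4% among 9759 genes, with 7.34% false. In 5 of the 6 simulated gene comparisons the false share was above 5%. Among 12118 promoters, 22.3% and 77.4% were recovered for JQ1 in AML3, with 12.3% of calls false. Among 704 enhancers, 4.71% and 17.6% were recovered for JQ1 in AML3. The simulated JQ1 interaction recovered 0% and 1.25% among 715 enhancers, and OTX015 against JQ1 in AML3 recovered 7.69% and 45.1% among 731. A simulated list of 25 genes shifted by 0.5 on the log2 scale was called with an adjusted p of 3.93e-12, and 0 of 20 unshifted lists were called. Genes were drawn independently of each other there, so this says nothing about false calls of lists with correlated members.

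Alternatives were DESeq2 1.42.0, its size factors in the edgeR fit, no filter on low counts, enhancers with at least 5 tags, enhancer library sizes from the enhancer table, a fit of the compared groups alone, a block for the replicate number, leaving out each library in turn, other distance limits, the fry test and estimated correlations for lists. Chosen after the data had been seen were a refit on replicates 1 and 2 alone, the enhancer share without the 10 most tagged enhancers and promoters, and annotated gene starts in place of promoters for proximity. No spike-in is named in the labels, so all values are relative. Shares of tags are relative to the same library, and CPM and fold changes also depend on the TMM factors. TMM scaling takes most genes as unchanged, which was not tested. In AML3, 50.8% of genes were called with JQ1 and 54.9% with OTX015.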

Results

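CAGE tags were counted at genes, promoters and enhancers in 18 libraries of the leukaemia lines AML2 and AML3, grown with vehicle, JQ1 or OTX015, with 3 libraries in each of the 6 groups. The gene table held 957036 to 2163106 tags per library in AML2 with vehicle, 570101 to 1290954 with JQ1 and 452667 to 1215251 with OTX015. In AML3 it held 822070 to 1864643 tags with vehicle, 378794 to 1024704 with JQ1 and 303883 to 800633 with OTX015. Between 11428 and 12562 genes had a tag in a library. The libraries numbered 3 were shallower, with a mean of 580758 gene tags against 1194919 and 1264786 for those numbered 1 and 2. On the principal components of the 2000 most variable genes, the drug libraries numbered 3 lay apart from the other 2 of their groups, while the vehicle libraries of each line lay close together. The long non-coding RNA MALAT1 took 0.102% to 0.29% of gene tags with vehicle and 1.41% to 6.75% with either compound.

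**Figure D1:**
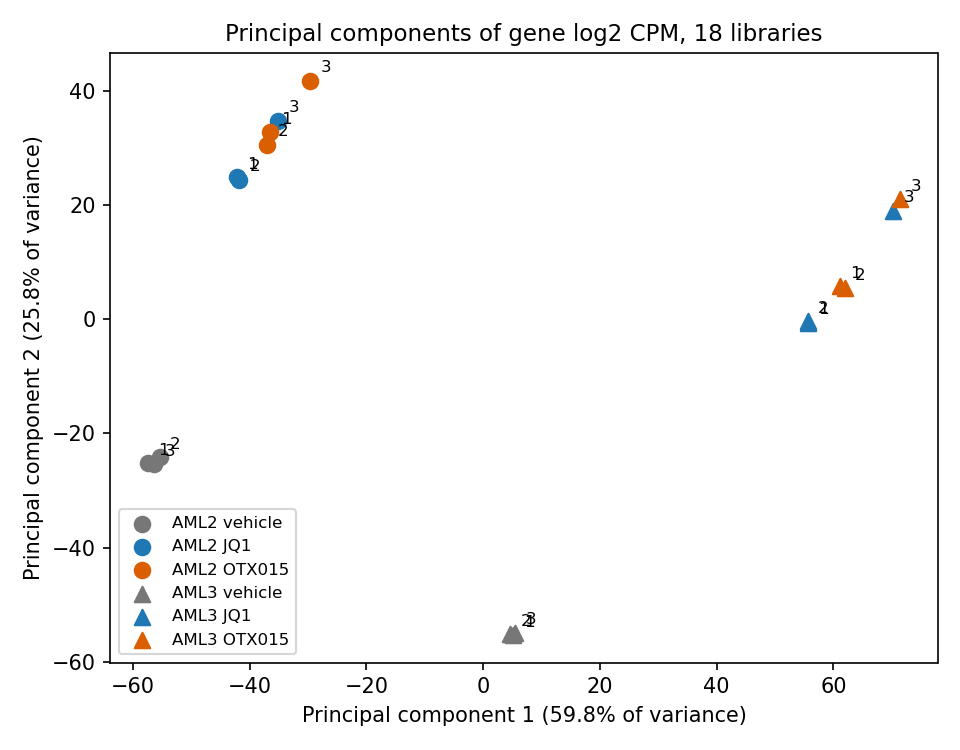
Principal component 1 (59.8% of the variance, horizontal) against component 2 (25.8%, vertical) of the log2 CPM of 2000 genes, with each point a library, coloured by group and numbered by replicate. The lines separate, as do drug and vehicle, while JQ1 and OTX015 libraries of a line lie near each other and those numbered 3 lie apart from the other libraries of their groups.

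The comparison of the lines with vehicle bears on what differs in a cell with mutated NPM1, the subject named in the series title, although the lines differ in much else. AML3 was higher for 1139 and lower for 1169 of 10031 genes, of which 867 and 736 differed at least 2-fold. TIMP3, an inhibitor of matrix metalloproteinases (GRCh38 chromosome 22, 32801701 to 32863043), had 0 tags in AML2 and 621 ± 166 CPM in AML3, at least 837-fold higher (adjusted p = 1.2e-10). The histone genes HIST3H2BB and HIST3H2A were at least 888-fold and 653-fold higher, and the RNA-binding protein gene IGF2BP2 at least 126-fold. PRTN3, which encodes a protease of primary granules, was 7.9 ± 3.53 CPM in AML2 and 323 ± 222 CPM in AML3 (log2 5.25, SE 0.52). Complement factor D (CFD) was 27.1 ± 15.2 and 841 ± 55.4 CPM (log2 4.90, SE 0.45). In the other direction, the homeobox gene PITX1 fell from 248 ± 46.1 CPM to 0, at least 310-fold, the potassium channel subunit gene KCNE5 at least 264-fold, and BCL7A, a subunit of a chromatin remodeller, at least 96.7-fold. MYC, the proliferation-driving transcription factor (GRCh38 chromosome 8, 127735434 to 127741434), was 439 ± 29.6 CPM in AML2 and 191 ± 15.6 CPM in AML3 (log2 −1.20, SE 0.22, adjusted p = 0.000168). NPM1 itself was 2900 ± 456 and 1907 ± 147 CPM, which did not pass the test (adjusted p = 0.243).

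Among the lists, HOX and MEIS genes, which set positional identity and self-renewal, went both ways between the lines. Of 12 tested, 5 were higher and 5 lower in AML3 (5 and 6 adjusted over the list alone, camera adjusted p = 0.945). HOXA13 had 0 tags in AML2 and 41.1 ± 6.42 CPM in AML3, at least 53.8-fold higher, and HOXB3 was at least 19.2-fold higher. HOXA9 was 121 ± 13.4 and 76.5 ± 16.3 CPM, which did not pass the test (adjusted p = 0.0762). MHC class II genes, which present antigen, were lower in AML3, 3 of 3 tested (3 adjusted over the list alone, camera adjusted p = 0.00126, adjusted p = 0.374 with an estimated correlation). The chaperone gene CD74 fell from 340.5 ± 101.2 to 88.5 ± 17.7 CPM (log2 −1.93, SE 0.30), and HLA-DRA was at least 53.3-fold lower. Of 39 MYC target and nucleolar genes, 11 were lower in AML3 and 0 higher (11 adjusted over the list alone, camera adjusted p = 0.0104, adjusted p = 0.985 with an estimated correlation), among them ODC1, the first enzyme of polyamine synthesis (log2 −1.10, SE 0.25). That list did not pass without AML2 vehicle replicate 3 (adjusted p = 0.195), which left 1 called list, or with replicates 1 and 2 alone (adjusted p = 0.0852). Of 17 monocyte and macrophage genes, 7 were higher and 4 lower (9 and 5 adjusted over the list alone, camera adjusted p = 0.301), with MNDA, a nuclear protein of myeloid cells, at 15.5 ± 5.41 CPM in AML2 and 102 ± 6.05 CPM in AML3 (log2 2.77, SE 0.29). In all, 2 of the 21 lists tested were called for the lines. Replication-dependent histone genes, not called, passed without AML3 vehicle replicate 3 (adjusted p = 0.00769) and with replicates 1 and 2 alone (0.00039).

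JQ1 in AML2 was compared with vehicle to find what BET bromodomain occupancy changes in the line without NPM1c. It raised 1727 and lowered 1742 of 10031 genes. MYC fell from 439 ± 29.6 to 66.6 ± 16.5 CPM (log2 −2.74, SE 0.24, adjusted p = 4.8e-09). BCL2, which blocks apoptosis, fell from 89.5 ± 7.85 to 27.8 ± 14.4 CPM (log2 −1.77, SE 0.27). HEXIM1, an inhibitor of the elongation factor P-TEFb and a common marker of BET inhibition, rose from 17.6 ± 8.27 to 150 ± 67 CPM (log2 3.16, SE 0.51, adjusted p = 2.9e-05). HEXIM1 was highest in the library numbered 3 of each drug group. SRD5A1, a steroid 5-alpha reductase, rose from 4 ± 2.62 to 343 ± 117 CPM (log2 6.18, SE 0.40), the transcription factor gene KLF2 by 5.52 (SE 0.47) and the integrin gene ITGB3 from 0 tags to 25 ± 17 CPM, at least 27.1-fold. NFKBIA, which encodes an inhibitor of NF-kB, rose from 20.3 ± 7.7 to 368 ± 38.4 CPM (log2 4.19, SE 0.30). MS4A3, a marker of granulocyte progenitors, fell from 219 ± 41.4 to 11.4 ± 5.59 CPM (log2 −4.36, SE 0.33). NPM3, a relative of NPM1 that works in the nucleolus, fell from 375 ± 28 to 26.6 ± 2.95 CPM (log2 −3.83, SE 0.29). NPM1 fell from 2900 ± 456 to 1192 ± 96.6 CPM (log2 −1.28, SE 0.36, adjusted p = 0.00751). With replicates 1 and 2 alone, 3965 genes passed in place of 3469.

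JQ1 in AML3, the same question in the line with NPM1c, raised 2685 and lowered 2414 genes. CTSG, the granule protease cathepsin G (GRCh38 chromosome 14, 24573522 to 24576260), fell from 3154 ± 901 to 22.2 ± 15.1 CPM (log2 −7.05, SE 0.52, adjusted p = 4.3e-10). PRTN3 fell from 323 ± 222 to 6.28 ± 2.64 CPM (log2 −5.57, SE 0.57). MYC fell from 191 ± 15.6 to 69.6 ± 6.87 CPM (log2 −1.47, SE 0.24, adjusted p = 1.8e-05), BCL2 from 66.4 ± 4.85 to 9.98 ± 1.33 CPM (log2 −2.73, SE 0.32). MYB, a transcription factor of progenitors, fell from 102 ± 23.5 to 44.3 ± 11.5 CPM (log2 −1.18, SE 0.30), and NPM1 from 1907 ± 147 to 773 ± 303 CPM (log2 −1.30, SE 0.36). HEXIM1 rose from 15.8 ± 6.18 to 378 ± 224 CPM (log2 4.57, SE 0.51), which was 3.98 without AML3 JQ1 replicate 3. SGK1, a kinase downstream of PI3K, rose from 0 tags to 63.3 ± 38.2 CPM, at least 65.2-fold, SLFN5 at least 40.8-fold and ATP8B1, a phospholipid flippase, at least 34.4-fold. SERPINI1, another marker of BET inhibition, rose from 0.772 ± 0.88 to 26.5 ± 1.76 CPM, a ratio of 31.7 (95% counting interval 10.4 to 157). CDK6, a cell-cycle kinase, rose from 41.6 ± 14.4 to 140 ± 120 CPM (log2 1.72, SE 0.46, adjusted p = 0.00286), a call that ended without AML3 JQ1 replicate 3 (log2 0.81, adjusted p = 0.0816). The selectin ligand gene SELPLG fell from 26.9 ± 2.9 CPM to 0, at least 24.3-fold. With replicates 1 and 2 alone, 5091 genes passed in place of 5099.

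**Figure D2:**
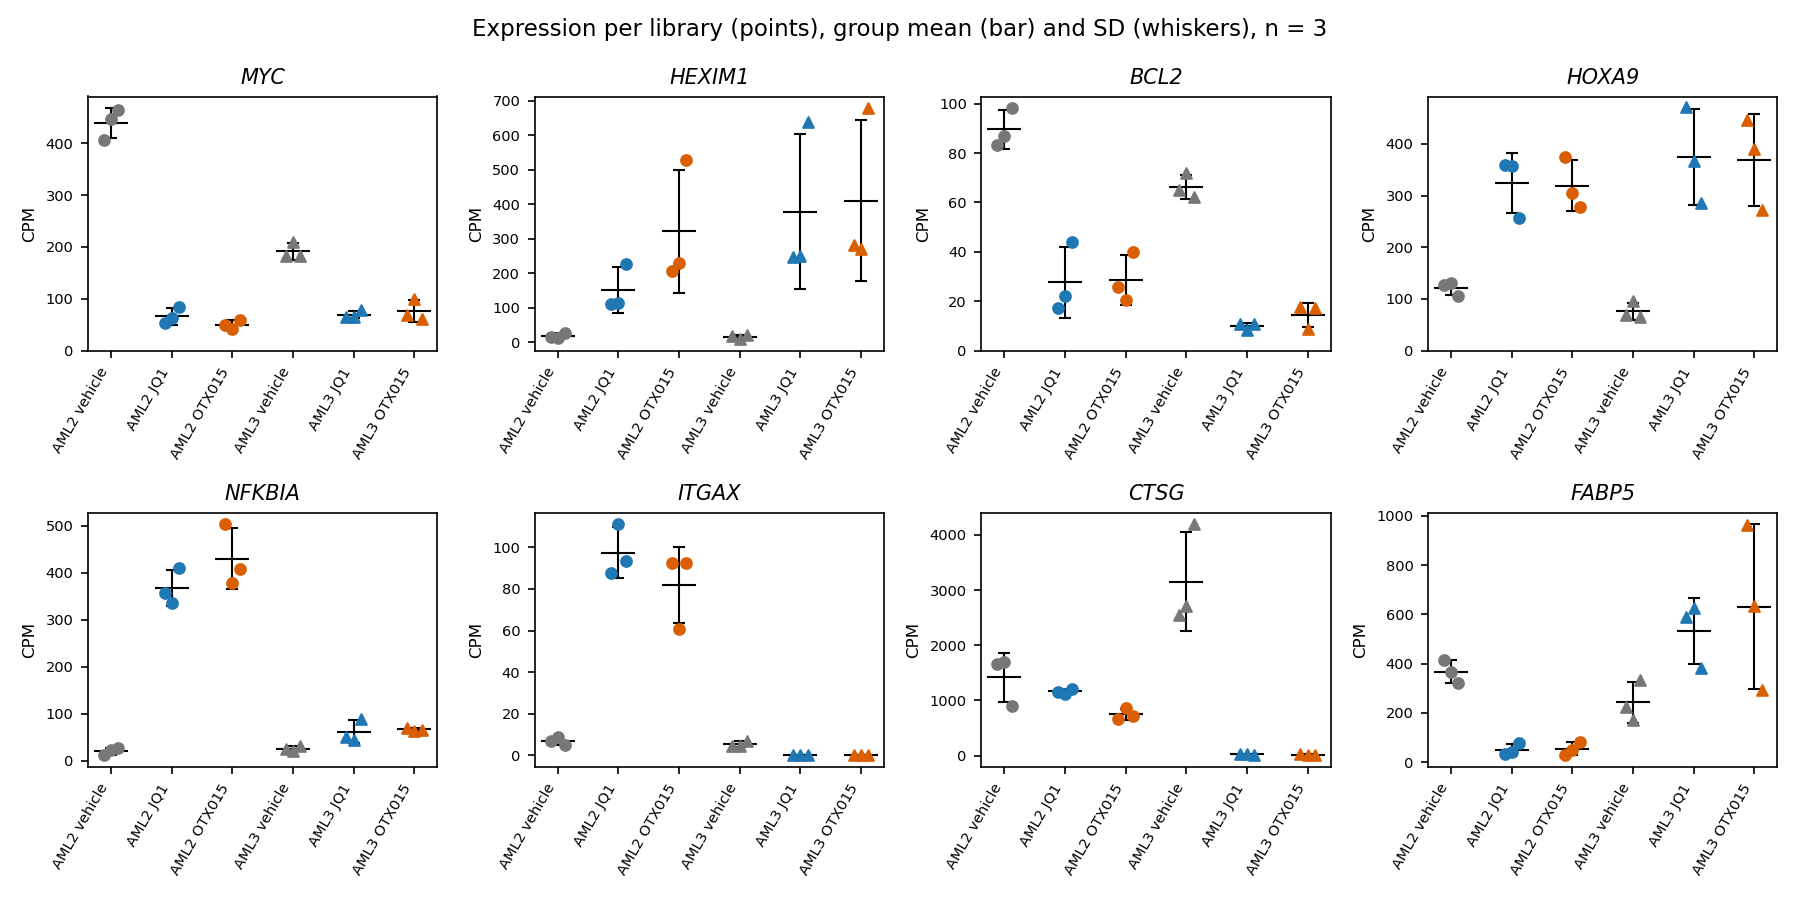
Levels in CPM (vertical) of MYC, HEXIM1, BCL2, HOXA9, NFKBIA, ITGAX, CTSG and FABP5 in the 6 groups (horizontal), with points for libraries, bars for means and whiskers for the SD over 3 libraries. MYC and BCL2 are lower and HEXIM1 and HOXA9 higher with both compounds in both lines, while ITGAX rises in AML2 alone and falls to 0 in AML3.

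OTX015, a clinical compound of the same class, was set against the same vehicle libraries. In AML2 it raised 2053 and lowered 1993 genes. MYC fell from 439 ± 29.6 to 50.3 ± 8.68 CPM (log2 −3.15, SE 0.25, adjusted p = 6.7e-10), NPM3 from 375 ± 28 to 14 ± 5.08 CPM (log2 −4.64, SE 0.32), and BCL2 to 28.7 ± 10.2 CPM (log2 −1.72, SE 0.27). HEXIM1 rose to 321 ± 179 CPM (log2 4.25, SE 0.51), SRD5A1 to 410 ± 140 CPM (log2 6.43, SE 0.40), ITGB3 from 0 tags to 39.5 ± 19.1 CPM, at least 45.1-fold, and NFKBIA to 430 ± 65.2 CPM (log2 4.42, SE 0.30). CCDC26, a long non-coding RNA near MYC, fell from 29.5 ± 14.5 CPM to 0, at least 25.6-fold. In AML3 OTX015 raised 2886 and lowered 2619 genes. CTSG fell to 14.6 ± 9.14 CPM (log2 −7.63, SE 0.54), PRTN3 to 2.19 ± 1.89 CPM (log2 −6.91, SE 0.68) and the metal-binding protein gene MT1F from 133 ± 24.6 to 1.82 ± 1.67 CPM (log2 −5.86, SE 0.40). CCDC26 fell from 39.1 ± 26.6 CPM to 0, at least 34.9-fold, MYC to 76.3 ± 20.7 CPM (log2 −1.31, SE 0.23), and MYB to 49.6 ± 13.1 CPM (log2 −1.07, SE 0.30). SGK1 rose to 88.1 ± 56.2 CPM, at least 89.7-fold, and HEXIM1 to 410 ± 232 CPM (log2 4.69, SE 0.52). With replicates 1 and 2 alone, 4444 genes passed in AML2 in place of 4046, and 5636 in AML3 in place of 5505.

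Genes of BET proteins responded as well. BRD3 rose in AML2 from 45.5 ± 5.1 to 77.5 ± 6.98 CPM with JQ1 (log2 0.75, SE 0.21) and to 81.7 ± 8.75 CPM with OTX015 (log2 0.84, SE 0.21). BRD2 rose in AML3 with OTX015 from 27.3 ± 1.97 to 59.7 ± 15.7 CPM (log2 1.07, SE 0.31, adjusted p = 0.00545). In AML3 BRD3 was 49.4 ± 4.15 CPM with vehicle, 52.5 ± 9.04 with JQ1 and 41.8 ± 14.3 with OTX015, which did not pass the test. Of the 25 BET proteins and elongation factors tested, 7, 11, 8 and 10 rose and 0, 3, 2 and 3 fell for JQ1 in AML2, JQ1 in AML3, OTX015 in AML2 and OTX015 in AML3, and the list was not called (camera adjusted p = 0.0809, 0.329, 0.102 and 0.373), although for JQ1 in AML2 it passed without a filter on low counts (0.0425). AFF4, a scaffold of the super elongation complex, rose with JQ1 in AML3 from 21.4 ± 7.96 to 56.8 ± 12.1 CPM (log2 1.30, SE 0.27).

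In the account of gene lists that follows, runs of 4 values are in that same order: JQ1 in AML2, JQ1 in AML3, OTX015 in AML2 and OTX015 in AML3. MYC target and nucleolar genes, which build ribosomes, fell in both lines. Of 39 tested, 37, 34, 37 and 31 fell and 0 rose (37, 35, 37 and 32 fell adjusted over the list alone, camera adjusted p = 1.4e-16, 4.95e-10, 1.37e-17 and 5.81e-09). The adjusted p with an estimated correlation was 0.016, 0.108, 0.0131 and 0.107. NOP16, a nucleolar protein gene, fell with OTX015 in AML2 from 264 ± 43.1 to 35.6 ± 5.14 CPM (log2 −2.88, SE 0.23). CDK4, a kinase of the G1 phase, fell with JQ1 in AML3 from 160 ± 23.6 to 35.5 ± 12 CPM (log2 −2.10, SE 0.23). Of 77 ribosomal protein genes, 8, 39, 10 and 54 fell and 0 rose (5, 39, 7 and 58 adjusted over the list alone, camera adjusted p = 0.00102, 4.66e-10, 1.6e-04 and 1.3e-10). Ribosomal protein genes gave adjusted p = 0.758, 0.473, 0.65 and 0.488 with an estimated correlation. RPL21 fell with JQ1 from 171 ± 27.4 to 44.9 ± 13.9 CPM in AML2 and from 100.7 ± 8.32 to 28.3 ± 6.16 CPM in AML3. Of 21 cholesterol synthesis genes, 19, 17, 15 and 15 fell and 1, 1, 0 and 1 rose (19, 17, 17 and 16 fell and 1, 1, 0 and 1 rose adjusted over the list alone, camera adjusted p = 5.58e-09, 3.26e-06, 1.87e-07 and 8e-05). Cholesterol synthesis genes gave adjusted p = 0.0598, 0.201, 0.102 and 0.28 with an estimated correlation. HMGCS1, an early enzyme of the pathway, fell with JQ1 in AML2 from 109 ± 22.8 to 17.8 ± 5.31 CPM (log2 −2.66, SE 0.30). FDPS, farnesyl diphosphate synthase, fell with JQ1 in AML3 from 448 ± 130 to 54 ± 20.9 CPM (log2 −3.01, SE 0.29).

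Genes of DNA replication and division fell as well. Of 29 S phase genes, 17, 25, 21 and 25 fell and 2, 1, 2 and 2 rose (19, 25, 22 and 25 fell and 3, 1, 2 and 2 rose adjusted over the list alone, camera adjusted p = 3.4e-04, 4.66e-10, 6.37e-05 and 1e-10). S phase genes gave adjusted p = 0.198, 0.108, 0.165 and 0.107 with an estimated correlation. MCM5, a subunit of the replicative helicase, fell in AML3 from 125 ± 29.3 to 24.8 ± 5.04 CPM with JQ1 (log2 −2.29, SE 0.24) and to 12.7 ± 0.566 CPM with OTX015 (log2 −3.27, SE 0.27). In AML2 the cyclin gene CCNE2 rose with JQ1 from 18 ± 1.39 to 41.2 ± 4.4 CPM (log2 1.17, SE 0.26). Of 28 mitosis genes, 15, 26, 19 and 27 fell and 0 rose (17, 28, 19 and 28 adjusted over the list alone, camera adjusted p = 2.79e-04, 4.12e-10, 4.74e-05 and 2.01e-11). Mitosis genes gave adjusted p = 0.41, 0.201, 0.36 and 0.189 with an estimated correlation. The mitotic kinase gene PLK1 fell by 1.39 (SE 0.25) with JQ1 in AML2 and by 2.28 (SE 0.29) with JQ1 in AML3. Of 37 replication-dependent histone genes, 3, 33, 5 and 34 fell and 0 rose (3, 34, 2 and 35 adjusted over the list alone, camera adjusted p = 0.00856, 2.06e-10, 0.00281 and 1.36e-12). Histone genes gave adjusted p = 0.748, 0.359, 0.635 and 0.28 with an estimated correlation. HIST1H2BM fell with JQ1 in AML3 from 1279.6 ± 378 to 251 ± 83.5 CPM (log2 −2.34, SE 0.41). In AML2 the histone list did not pass without JQ1 replicate 3 (adjusted p = 0.137) or without OTX015 replicate 3 (adjusted p = 0.265), nor with replicates 1 and 2 alone (0.163 and 0.433).

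HOX and MEIS genes rose with both compounds, 6, 7, 6 and 7 of 12, while 0, 1, 0 and 1 fell (the same counts adjusted over the list alone, camera adjusted p = 0.00369, 0.00967, 0.00509 and 0.00602). HOX and MEIS genes gave adjusted p = 0.0598, 0.138, 0.0777 and 0.107 with an estimated correlation. HOXA9, a transcription factor of leukaemic self-renewal, rose with JQ1 from 121 ± 13.4 to 325 ± 58.1 CPM in AML2 (log2 1.42, SE 0.26) and from 76.5 ± 16.3 to 375 ± 93.3 CPM in AML3 (log2 2.29, SE 0.27). Its cofactor gene MEIS1 rose from 24.2 ± 5.36 to 92.9 ± 7.37 CPM (log2 1.89, SE 0.21) and from 19.7 ± 4.28 to 42.7 ± 7.15 CPM (log2 1.12, SE 0.24). HOXB3 rose with JQ1 in AML3 from 15.1 ± 3.43 to 194 ± 23.3 CPM (log2 3.66, SE 0.24). In AML3 the list did not pass without a filter on low counts (adjusted p = 0.165 and 0.249). Of 15 BET-dependent leukaemia genes, 3, 9, 4 and 10 fell and 4 rose in each comparison; adjusted over the list alone, 10 and 11 fell in AML3. The list was lower in AML3 (camera adjusted p = 0.0136 and 0.0207, adjusted p = 0.292 and 0.28 with an estimated correlation) and not called in AML2 (0.773 and 0.525). With replicates 1 and 2 alone it did not pass for OTX015 in AML3 (adjusted p = 0.107). The myeloid transcription factor genes IRF8 and SPI1 fell with OTX015 in AML3 by 2.16 (SE 0.25) and 2.39 (SE 0.30), while in AML2 the receptor kinase gene FLT3 rose with JQ1 by 1.58 (SE 0.23) and LMO2, a transcriptional bridging factor, by 1.78 (SE 0.27).

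Genes of myeloid maturation moved apart. Primary granule and progenitor genes fell in both lines, 7, 9, 7 and 9 of 12, and 1 rose in each comparison (7, 9, 9 and 9 fell and 1 rose adjusted over the list alone, camera adjusted p = 2.79e-04, 2.12e-05, 2e-04 and 1.32e-05). Granule genes gave adjusted p = 0.178, 0.2, 0.165 and 0.176 with an estimated correlation. AZU1, an antimicrobial granule protein, fell with JQ1 in AML2 from 1243 ± 585 to 217 ± 7.88 CPM (log2 −2.52, SE 0.32). SRGN, the granule proteoglycan, fell with JQ1 in AML3 from 1599 ± 170 to 165 ± 55.4 CPM (log2 −3.27, SE 0.38). Of 17 monocyte and macrophage genes, 9 rose and 2 fell with JQ1 in AML2 and 8 rose and 3 fell with OTX015 (camera adjusted p = 0.0112 and 0.0235, adjusted p = 0.214 and 0.303 with an estimated correlation). In AML3, 2 rose and 7 fell with JQ1 and 2 rose and 9 fell with OTX015 (adjusted p = 0.0262 and 0.0112, adjusted p = 0.359 and 0.28 with an estimated correlation). Counts adjusted over the list alone were the same. The alarmin gene S100A8 rose with JQ1 in AML2 from 215 ± 88.9 to 1537 ± 201.85 CPM (log2 2.85, SE 0.50). The Fc receptor gene FCGR2A fell with JQ1 in AML3 from 81 ± 29.9 to 8.32 ± 2.76 CPM (log2 −3.21, SE 0.36). The list did not pass for JQ1 in AML2 without JQ1 replicate 3 (adjusted p = 0.0627), for JQ1 in AML3 without JQ1 replicate 2 (0.0558), or for OTX015 in AML2 without vehicle replicate 2 (0.0638) or OTX015 replicate 3 (0.0961).

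Inflammatory and lysosomal genes rose in AML2, and more regulators of apoptosis rose than fell. Such regulators can promote or block apoptosis, so their list gives no direction for cell death. Of 22 NF-kB and inflammatory genes, 16 rose and 0 fell in AML2 with each compound (17 rose adjusted over the list alone, camera adjusted p = 1.42e-08 and 4.92e-08, adjusted p = 0.00908 and 0.011 with an estimated correlation). In AML3, 9 and 10 rose and 6 and 6 fell, and the list was not called (adjusted p = 0.329 and 0.373). The cytokine gene TNF rose with JQ1 in AML2 from 64.7 ± 29.4 to 779 ± 112 CPM (log2 3.62, SE 0.42), and ICAM1, an adhesion molecule, by 4.14 (SE 0.49). Of 27 lysosome and autophagy genes, 15 and 16 rose and 0 fell in AML2 (17 and 19 rose adjusted over the list alone, camera adjusted p = 5e-06 and 1.5e-05, adjusted p = 0.016 and 0.0217 with an estimated correlation). In AML3 10 rose with each compound (10 and 9 adjusted over the list alone) and the list was not called (adjusted p = 0.112 and 0.138), but it passed without AML3 JQ1 replicate 3 (0.0346), without AML3 OTX015 replicate 3 (0.042) and with replicates 1 and 2 alone (0.0134 and 0.0227). The autophagy gene GABARAPL1 rose with JQ1 by 2.78 (SE 0.29) in AML2 and by 2.37 (SE 0.27) in AML3. Of 16 apoptosis regulator genes, 8 rose in AML2 with each compound and 1 and 2 fell (8 rose and 1 and 3 fell adjusted over the list alone, camera adjusted p = 0.0173 and 0.0337, adjusted p = 0.0598 and 0.102 with an estimated correlation). The OTX015 call ended without AML2 vehicle replicate 2 (adjusted p = 0.0638), and in AML3 6 and 7 rose and 3 and 4 fell (9 and 7 rose and 4 and 4 fell adjusted over the list alone, camera adjusted p = 0.329 and 0.485). BMF, which promotes apoptosis, rose with JQ1 by 2.93 (SE 0.30) in AML2 and by 3.48 (SE 0.32) in AML3.

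Of 23 p53 target genes, 10, 11, 12 and 13 rose and 1, 1, 1 and 2 fell (10, 12, 12 and 13 rose and 2, 1, 1 and 2 fell adjusted over the list alone, camera adjusted p = 0.0247, 0.0092, 0.00649 and 0.00602). Genes of the p53 list gave adjusted p = 0.558, 0.428, 0.43 and 0.464 with an estimated correlation. BTG2, which slows proliferation, rose with JQ1 in AML2 from 8.56 ± 2.5 to 323 ± 152 CPM (log2 5.17, SE 0.53). TP53INP1, a stress-induced nuclear protein gene, rose with JQ1 in AML3 by 4.14 (SE 0.51). For JQ1 in AML2 the list did not pass without vehicle replicate 2 (adjusted p = 0.0937) or JQ1 replicate 3 (0.139). MHC class II genes, not called with drug (adjusted p = 0.246, 0.329, 0.123 and 0.409), fell in 2, 1, 2 and 1 of 3 members and passed in AML2 without vehicle replicate 3 (adjusted p = 0.0384 with JQ1 and 0.0181 with OTX015) and with replicates 1 and 2 alone (0.015 and 0.00628), and for OTX015 without a filter on low counts (0.0289). With DESeq2 neither member that fell with JQ1 in AML2 passed, HLA-DRA (adjusted p = 0.109) or HLA-DRB1 (0.0871), nor did HLA-DRA with OTX015 (0.114). HLA-DRB1 with JQ1 in AML2 also did not pass without vehicle replicate 1 (0.144) or 2 (0.0919) or JQ1 replicate 2 (0.157) or 3 (0.075). Not called were also 11 BET inhibitor induced genes, mostly linker and core histone genes (2, 4, 2 and 4 rose, 1, 4, 1 and 7 fell, adjusted p = 0.712, 0.812, 0.88 and 0.588), of which HIST1H2BK fell with JQ1 in AML3 (log2 −2.26, SE 0.41). The same held for 11 interferon response genes (3, 2, 4 and 2 rose, 1, 1, 3 and 1 fell, adjusted p = 0.143, 0.625, 0.419 and 0.763), although IRF7 rose with JQ1 by 3.45 (SE 0.40) in AML2 and by 3.28 (SE 0.34) in AML3. Of 24 integrated stress response genes, 4, 5, 4 and 6 rose and 5, 10, 6 and 9 fell (adjusted p = 0.512, 0.329, 0.623 and 0.409). The phosphatase subunit gene PPP1R15A rose with JQ1 in AML3 by 3.89 (SE 0.36), and PSAT1, of serine synthesis, fell by 3.02 (SE 0.39). Of 5 stem and progenitor score genes, 1, 0, 1 and 0 rose and 0, 1, 0 and 2 fell (adjusted p = 0.655, 0.23, 0.78 and 0.214). Of 4 lymphoid markers, 0, 1, 0 and 1 rose and 1, 2, 1 and 2 fell (adjusted p = 0.542, 0.645, 0.295 and 0.763). Adjusted over the list alone, the counts of lists that were not called were mostly the same; among the differences, 6 BET proteins and elongation factors and 5 interferon response genes rose with JQ1 in AML2, and 7 integrated stress response genes fell with OTX015 in AML2. Erythroid and megakaryocyte markers had 2 members tested, too few for the list test, and epithelial and fibroblast markers 0. In all 13, 11, 13 and 11 of 21 lists were called, with an estimated correlation 3, 0, 3 and 0, and with fry 13, 16, 15 and 17. The median, the mean and the test of a list differed in sign for some lists that were not called, and for none that was called.

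**Figure D3:**
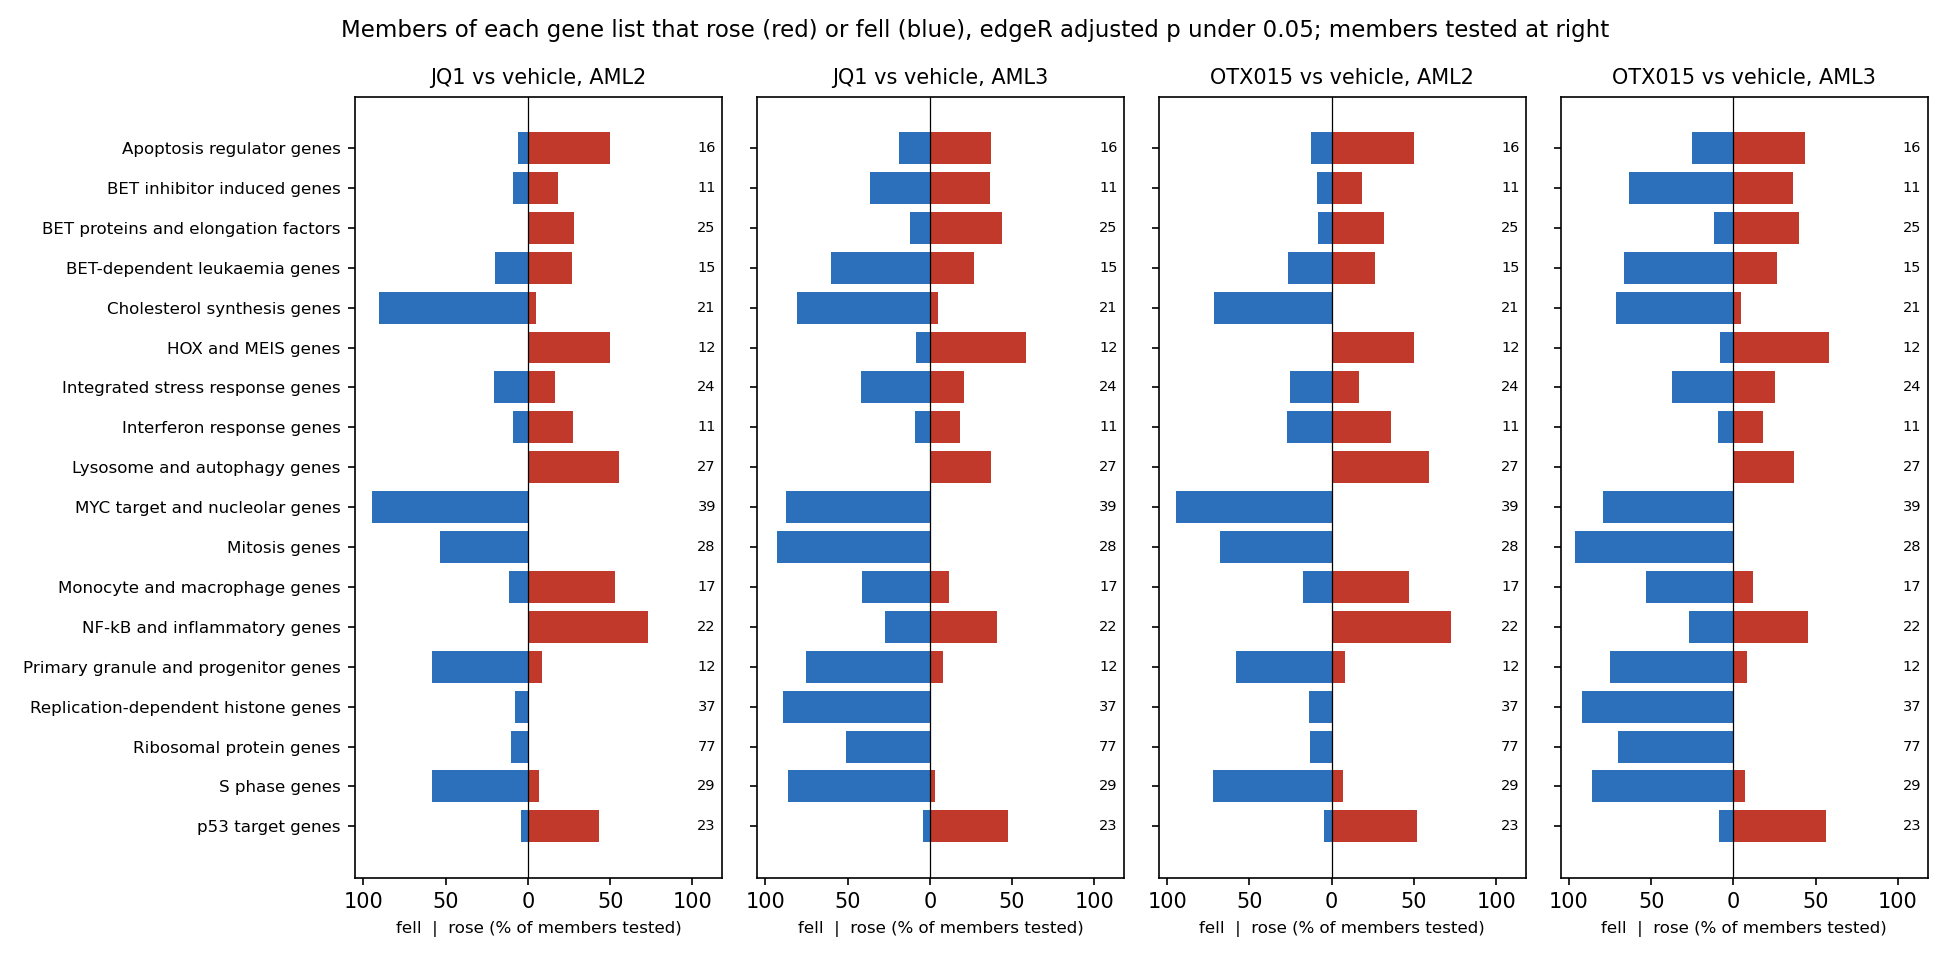
Percent of the tested members (horizontal) that rose or fell in each of 18 gene lists with at least 10 members tested (vertical, number tested at the right), in 4 panels for JQ1 and OTX015 in AML2 and AML3. MYC target genes fall in all 4 panels, and more monocyte and macrophage genes rise than fall in AML2 and more fall than rise in AML3.

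JQ1 and OTX015 were compared with each other in each line, at doses and times that the labels do not give. With edgeR, 0 of 10031 genes differed in either line. At an unadjusted p under 0.05 there were 331 in AML2 and 253 in AML3, each a smaller share than the 0.05 that unchanged genes give by chance. DESeq2 called 1 in AML2 and 0 in AML3. For MYC the log2 difference of OTX015 from JQ1 was −0.41 (95% interval −0.94 to 0.12) in AML2 and 0.16 (−0.35 to 0.67) in AML3, and neither passed the test. HEXIM1 differed by 1.10 (0.23 to 1.96, unadjusted p = 0.016, adjusted p = 1) in AML2 and 0.12 (−0.72 to 0.96) in AML3, and BCL2 by 0.05 (−0.60 to 0.70) and 0.50 (−0.37 to 1.36). HOXA9 differed by −0.02 (−0.55 to 0.50) in AML2 and −0.02 (−0.54 to 0.50) in AML3. The interval lay within 2-fold either way for 5808 genes (57.9%) in AML2 and 6000 genes (59.8%) in AML3, and so larger differences between the compounds are not excluded for the rest. Both compounds called the same direction for 3070 genes in AML2 (1518 higher, 1552 lower) and 4637 in AML3 (2443 higher, 2194 lower), and 0 genes were called in opposite directions. Independent lists of these sizes would share 354 higher and 346 lower genes in AML2 and 773 and 630.3 in AML3. Unchanged groups simulated against the same vehicle libraries shared 0 on average in AML2, which was fixed in advance, as no gene differed there. Log2 fold changes of the compounds correlated across genes, which are not independent replicates, with r = 0.932 in AML2 and 0.961 in AML3 (0.435 and 0.441 simulated). The covariance was 1.19 and 1.97 against 0.061 simulated in each line. The 3 vehicle libraries of a line cannot be split into parts of 2, so the part due to shared controls was judged by simulation alone. Less the simulated value, the covariance was 1.13 in AML2 and 1.91 in AML3.

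The difference of a compound's effect between the lines was tested directly. The JQ1 effect was higher in AML3 for 303 genes and lower for 393, and the OTX015 effect for 285 and 482. The JQ1 count of 696 was 462 without AML2 JQ1 replicate 2, and with replicates 1 and 2 alone the counts were 1263 and 1410. With a block for the replicate number they were 1149 and 1230. ITGAX, an integrin of monocytes and dendritic cells (GRCh38 chromosome 16, 31355134 to 31382997), rose in AML2 from 6.84 ± 1.79 CPM to 97.5 ± 12.1 with JQ1 and 81.9 ± 18.2 with OTX015, and in AML3 fell from 5.37 ± 1.5 CPM to 0 with both (adjusted p for the difference 3.78e-06 and 8.81e-06). CTSG was 1419.5 CPM with vehicle, 1162 with JQ1 and 749 with OTX015 in AML2, against 3154, 22.2 and 14.6 in AML3 (difference of log2 effects −6.76, SE 0.62, and −6.71, SE 0.63). FABP5, a fatty acid carrier, went from 367 ± 45.9 CPM to 50.5 ± 22.2 with JQ1 in AML2 and from 243 ± 82.4 to 532 ± 133 in AML3 (difference 4.05, SE 0.55). MYC fell less in AML3 than in AML2, by a difference of 1.27 (SE 0.33, adjusted p = 0.0166) with JQ1 and 1.84 (SE 0.34, adjusted p = 0.000737) with OTX015. The JQ1 difference of MYC did not pass without AML2 JQ1 replicate 1 (adjusted p = 0.0732), AML2 JQ1 replicate 2 (0.0591) or AML3 vehicle replicate 1 (0.052). By list, 9 of 17 monocyte and macrophage genes had a lower effect in AML3 with each compound and 0 a higher one (9 adjusted over the list alone), as did 8 of 22 NF-kB and inflammatory genes with each compound (10 and 12 adjusted over the list alone), 10 and 13 of 29 S phase genes (14 and 17) and 7 and 11 of 28 mitosis genes (11 and 18).

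The series title raises the question of how far BET inhibition returns the mutant line to an unaltered state. These data cannot answer it, as AML2 is a separate leukaemia line that differs in much else. Moves towards AML2 are therefore not moves to an unaltered state. Of the 2308 genes that differed between the lines with vehicle, JQ1 in AML3 moved 468 towards AML2 (265 higher genes fell and 203 lower genes rose) and 725 further away (375 and 350). OTX015 moved 501 towards AML2 (282 and 219) and 745 away (377 and 368). Towards AML2 went PRTN3, from 323 ± 222 to 6.28 ± 2.64 CPM with JQ1, where AML2 with vehicle had 7.9 ± 3.53. So did IRF8, from 1104 ± 111 to 241 ± 26.9 CPM against 390 ± 50.8, and the stress-response factor gene ATF5, from 9.43 ± 1.48 to 41.8 ± 7.02 CPM against 91.9 ± 14.1. Away from AML2 went HOXB3, from 15.1 ± 3.43 to 194 ± 23.3 CPM where AML2 had 0. So did MYC, from 191 ± 15.6 to 69.6 ± 6.87 CPM against 439 ± 29.6, and CD74, from 88.5 ± 17.7 to 20 ± 7.96 CPM against 340.5 ± 101.2. Independent lists would give 274 and 313 genes towards AML2 and 305 and 281 away for JQ1, and 297 and 336 towards and 328 and 305 away for OTX015. The counts towards AML2 lay below these values and those away above them. Groups simulated without any change against the same AML3 vehicle libraries gave 0.05 genes on average for JQ1. A count near 0 was fixed in advance there, as no gene differed, and is no measure for the counts found. The correlation of the line and drug changes across genes was 0.071 and 0.069, and the covariance 0.14 and 0.148. The simulated values, which hold only the noise of shared libraries, were −0.476 and −0.465 for the correlation and −0.068 and −0.069 for the covariance. Without AML3 vehicle replicate 1 the counts towards AML2 were 310.0 and 330.0, and without AML3 vehicle replicate 2 the JQ1 count was 311. Restricted to changes of at least 2-fold they were 279 and 314.

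At single promoters, 1379 were higher and 1450 lower in AML3 among 12867 tested. JQ1 raised 2199 and lowered 2323 in AML2 and raised 3413 and lowered 3062 in AML3, and OTX015 raised 2644 and lowered 2576 in AML2 and raised 3648 and lowered 3322 in AML3. The CTSG promoter (hg19 chromosome 14, 25045446 to 25045464, minus strand) fell in AML3 by 7.05 (SE 0.52) on the log2 scale with JQ1 and by 7.62 (SE 0.54) with OTX015. The ITGB3 promoter (hg19 chromosome 17, 45331184 to 45331200, plus strand) was at least 26.5-fold higher with JQ1 and at least 44.2-fold higher with OTX015 in AML2. Between the lines, the TIMP3 promoter (hg19 chromosome 22, 33197683 to 33197698, plus strand) was at least 828-fold higher in AML3 and the KCNE5 promoter (hg19 chromosome X, 108868390 to 108868407, minus strand) at least 267-fold lower. These promoters carried the counts of their genes. A promoter with no gene of equal counts (hg19 chromosome 6, 134495992 to 134496010, minus strand) rose in AML3 from 0 tags, at least 63.8-fold with JQ1 and at least 89.5-fold with OTX015. SGK1, on the same strand of chromosome 6, rose almost alike from 0 tags in AML3. Whether this promoter belongs to SGK1 was not tested, as builds were not converted, so the rise may be that of SGK1.

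Enhancers give short capped RNAs in proportion to their activity, and 849 were tested. Relative to promoter tags, JQ1 raised 97 and lowered 16 in AML2 and raised 274 and lowered 38 in AML3, while OTX015 raised 140 and lowered 21 in AML2 and raised 314 and lowered 41 in AML3. With library sizes from the enhancers themselves, which shifted the median log2 change by −0.53, −0.90, −0.64 and −1.07 in the order used for lists, the splits were 39 and 28, 88 and 85, 51 and 35, and 98 and 88. An enhancer 823 bases from the start of LMO2, between genes (hg38 chromosome 11, 33892999 to 33893225), rose in AML3 from 3.55 ± 1.84 to 126 ± 8.28 CPM with JQ1 (log2 4.97, SE 0.50) and to 113 ± 29.1 CPM with OTX015 (log2 4.83, SE 0.50). In AML2 the same enhancer rose from 0.767 to 104 CPM with JQ1, a ratio of 110.0 (95% counting interval 37.1 to 536), and by a ratio of 181 (61.6 to 884) with OTX015. Without AML2 vehicle replicate 1 its fitted log2 changes there, 6.76 and 7.46, were 7.60 and 8.30. A promoter on the minus strand, the strand of LMO2 (hg19 chromosome 11, 33914678 to 33914683), rose almost alike with OTX015 in AML2 (log2 7.37). Whether this promoter and the enhancer count the same start was not tested, as builds were not converted, so the rise may be that of an LMO2 promoter. An enhancer 1291 bases from the start of AZU1, between genes (hg38 chromosome 19, 823657 to 823955), was lower in AML2 by a ratio of 15.2 (4.99 to 75.7) with JQ1 and 20.9 (5.57 to 176) with OTX015. An enhancer in an intron of RXRA, a nuclear receptor gene (hg38 chromosome 9, 134372644 to 134373270), fell with JQ1 in AML3 from 26.5 ± 3.97 to 3.23 ± 2.34 CPM (log2 −3.18, SE 0.57). An enhancer in an intron of GTF2A1 (hg38 chromosome 14, 81219169 to 81219729) rose with OTX015 in AML3 by 4.70 (SE 0.50). An enhancer in an intron of the non-coding gene CCDC26 (hg38 chromosome 8, 129554562 to 129555050) was at least 5.28-fold lower with OTX015 in AML2. In AML2 the JQ1 count of 113 was 69 without vehicle replicate 1, 58 without vehicle replicate 2 and 75 without JQ1 replicate 2. The OTX015 count of 161 was 105 without vehicle replicate 1, 85 without vehicle replicate 2 and 107 without OTX015 replicate 2.

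Between the lines, 68 enhancers were higher and 39 lower in AML3 with vehicle. An enhancer in an intron of PRAM1, a myeloid adaptor gene (hg38 chromosome 19, 8500051 to 8500446), was 29 CPM in AML2 and 2.46 CPM in AML3 (log2 −3.45, SE 0.54). An enhancer named in hg19 (chromosome 16, 89268043 to 89268411) was at least 22.9-fold higher in AML3. The count of 107 was 70 without AML2 vehicle replicate 1, 58 without AML2 vehicle replicate 2, 60 without AML3 vehicle replicate 1 and 61 without AML3 vehicle replicate 2. For OTX015 against JQ1, edgeR called 0 of 849 enhancers in each line, with 35 in AML2 and 14 in AML3 at an unadjusted p under 0.05 and 0 by DESeq2. Those 35 and 14 are smaller shares than the 0.05 that chance gives. The effect of JQ1 differed between the lines at 6 enhancers and that of OTX015 at 3, where the simulated JQ1 interaction recovered 1.25% of 4-fold changes. Both counts were 0 with DESeq2 and 0 with no filter on low counts. The JQ1 count was 0 without AML2 vehicle replicate 1, AML3 vehicle replicate 1 or 2 or AML3 JQ1 replicate 2, 1 without AML2 vehicle replicate 2, 2 without AML2 JQ1 replicate 1, 3 without AML2 JQ1 replicate 2 or AML3 vehicle replicate 3 and 10 without AML2 vehicle replicate 3. The OTX015 count was 0 without AML3 vehicle replicate 2 or AML3 OTX015 replicate 2 and 1 without AML2 vehicle replicate 1 or AML3 vehicle replicate 1 or 3.

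Enhancer tags made up 0.241% ± 0.026 (SD, n = 3) of enhancer and promoter tags in AML2 with vehicle, 0.49% ± 0.0688 with JQ1 and 0.551% ± 0.0783 with OTX015. In AML3 the share was 0.311% ± 0.0228 with vehicle, 0.94% ± 0.386 with JQ1 and 1.05% ± 0.306 with OTX015. The ratios to vehicle were 2.03 and 2.28 in AML2 and 3.02 and 3.37 in AML3, and the AML3 share with vehicle was 1.29 times that of AML2. In each of the 5 comparisons the libraries did not overlap and the two-sided exact permutation p was 0.1, the smallest that 3 against 3 libraries can give (0.1 adjusted), and chance gives such a separation in 10% of cases. The libraries numbered 3 were highest in AML3, at 1.39% (Wilson 95% interval 1.35 to 1.42) with JQ1 against 0.729% and 0.706%, and at 1.4% (1.36 to 1.44) with OTX015 against 0.872% and 0.873%. Without them the ratios were 2.3 and 2.8, and the differences from vehicle, 0.629 and 0.738 percentage points, were 0.406 and 0.561. Enhancers and promoters were paired only within the same build, and promoters closer than 1 kb were passed over. Only 826 of 42133 promoters carry hg38 coordinates, so the promoter paired with an hg38 enhancer may not be its nearest. There were 159 enhancers with a tested promoter of the same build 1 to 100 kb away. Those whose nearest such promoter fell with OTX015 in AML2 fell in 4 of 24 cases, against 4 of 135 others (odds ratio 6.55, Fisher's exact p = 0.0188, adjusted p = 0.075). Odds ratios were 2.71 for JQ1 in AML2 (1 of 18 against 3 of 141, adjusted p = 0.385), 2.13 for JQ1 in AML3 (3 of 28 against 7 of 131, 0.385) and 3.02 for OTX015 in AML3 (3 of 28 against 5 of 131, 0.296), and none passed the test. For OTX015 in AML2 the ratio was 1.88 without OTX015 replicate 3, 2.54 without OTX015 replicate 1, 3.48 without OTX015 replicate 2 and 4.31 without vehicle replicate 2. For JQ1 in AML2 it was 0 without JQ1 replicate 1 or 2, and 6.33 without JQ1 replicate 3, 18.5 without vehicle replicate 1, 7.2 without vehicle replicate 2 and 5.11 without vehicle replicate 3. For JQ1 in AML3 it was 1.075 without JQ1 replicate 1 or 2, 1.2 without JQ1 replicate 3 and 1.38 without vehicle replicate 1, and for OTX015 in AML3 it was 1.5 without OTX015 replicate 3. With annotated gene starts in place of promoters (516 enhancers, all read as hg38 and so another set) it was 3.59 for OTX015 in AML2 and 1.86 for OTX015 in AML3. At 1 to 500 kb it was 1.62 for JQ1 in AML2 and 3.32 for JQ1 in AML3, and at 1 to 50 kb it was 0 for JQ1 in AML2.

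**Figure D4:**
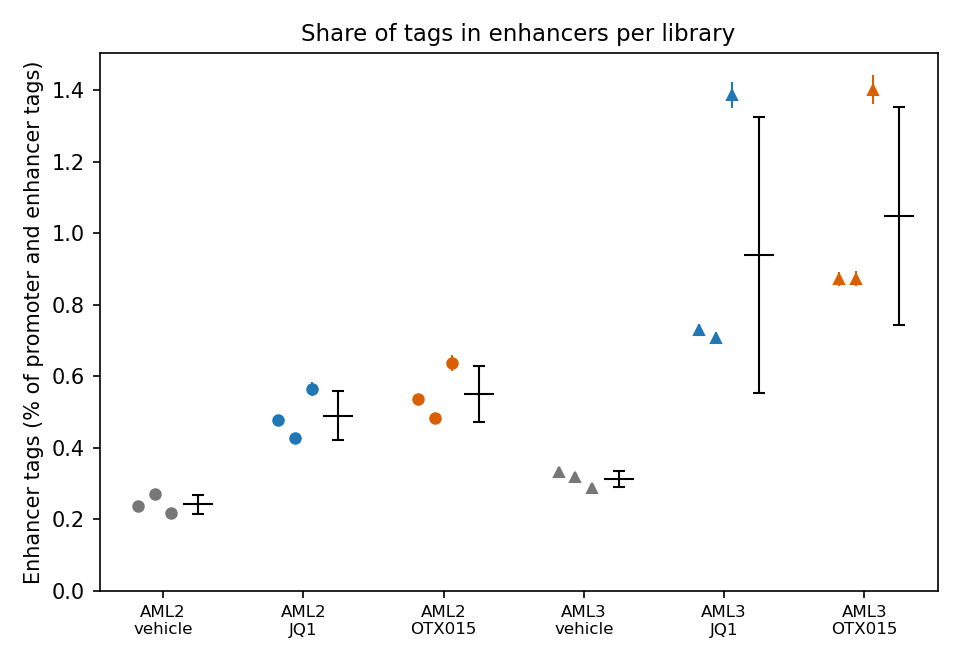
Enhancer tags as a percent of enhancer and promoter tags (vertical) in each library of the 6 groups (horizontal), with Wilson 95% intervals for libraries and the mean and SD of each group. The share is above vehicle in all drug libraries of each line, and highest in the AML3 drug libraries numbered 3.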

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

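Of the tests in this part, the refit on replicates 1 and 2 alone, the count of groupings that relabelled both lines and the rule that a setting must move the count over all genes by at least 5% to test an explanation were chosen after the results had been seen. Not foreseen was that the lines would respond to a compound in opposite directions at some genes. The JQ1 effect differed between the lines at 696 genes and 6 enhancers, and the OTX015 effect at 767 genes and 3 enhancers. These counts take in differences of size as well as of direction, and opposite directions were not counted apart. ITGAX, an integrin of monocytes (adjusted p = 3.78e-06 with JQ1 and 8.81e-06 with OTX015), and GPR84, a receptor for medium-chain fatty acids (8.6e-09 and 7.21e-09), rose in AML2 and were almost absent from AML3 with drug. GPR84 went from 25.8 to 194 CPM with JQ1 in AML2 and from 29.2 to 0.593 CPM in AML3. CYTIP, which regulates adhesion of leukocytes (0.000107 and 0.000212), HK3, a hexokinase of myeloid cells (0.00176 with JQ1), and HVCN1, a proton channel (9.74e-05 with OTX015), followed the same course. CTSG, the granule protease (7.67e-08 and 1.12e-07), fell in AML3 and did not pass the test in AML2.

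The other direction was seen at FABP5, a fatty acid carrier (2.37e-05 with JQ1), which fell in AML2 and rose in AML3. For FSCN1, RNF144A, PKIB, FMNL2 and IRS1 the effect was higher in AML3, which need not mean opposite directions. FSCN1, an actin bundling protein (0.00063 with JQ1 and 0.000183 with OTX015), went from 0.195 to 10.8 CPM with JQ1 in AML3. RNF144A, a ubiquitin ligase (9.92e-05 with OTX015), went from 2.3 to 47.8 CPM in AML3. PKIB, an inhibitor of protein kinase A (0.00116 and 0.000995), fell in AML2 from 44.4 to 3.7 CPM with JQ1. FMNL2, a formin (0.00281 and 0.00833), and IRS1, an adaptor of insulin signalling (0.0125 and 0.00928), were higher with drug in AML3. FMNL2 did not pass without AML2 vehicle replicate 2 (0.0553 and 0.137), nor IRS1 with JQ1 without AML2 JQ1 replicate 2 (0.052). MYC fell less in AML3 (0.0166 with JQ1 and 0.000737 with OTX015), and the JQ1 call ended without AML2 JQ1 replicate 1 (0.0732), AML2 JQ1 replicate 2 (0.0591) or AML3 vehicle replicate 1 (0.052). BRD3, a BET protein, differed with OTX015 (0.046), a call that ended without any 1 of 10 of the 12 libraries, all but AML2 OTX015 replicate 3 and AML3 OTX015 replicate 1 (0.0708 to 0.11).

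Enhancers where the JQ1 effect was higher in AML3 lay at hg38 chromosome 1, 31154719 to 31155112 (84639 bases from NKAIN1, adjusted p = 0.0384), hg38 chromosome X, 107676773 to 107677571 (48748 bases from PRPS1, 0.0458) and hg19 chromosome 1, 232765644 to 232766127 (0.0458). It was lower in AML3 at hg38 chromosome 15, 31266255 to 31266769 (60343 bases from KLF13, 0.024), hg38 chromosome 19, 8576584 to 8576951 (an exon of MYO1F, 0.024) and hg19 chromosome 2, 106412674 to 106413002 (0.024). The OTX015 effect was higher in AML3 at hg19 chromosome 16, 2955389 to 2955781 (0.0227). It was lower at hg38 chromosome 19, 8500051 to 8500446 (an intron of PRAM1, 0.021), and at the MYO1F exon (0.021). Each of these calls ended on leaving out any of at least 4 single libraries.

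Monocyte and macrophage genes carried part of the difference, with a lower effect in AML3 at 9 of 17 for each compound. If the libraries numbered 3, which stood apart, had made it, the calls would end without them. With replicates 1 and 2 alone 9 of 9 calls remained for JQ1 and 8 of 9 for OTX015, so that explanation does not account for them. Library scaling stays open. With DESeq2 size factors 9 of 9 remained for both compounds, but these changed the count over all genes only from 696 to 692 for JQ1 and so are no test of it. Why the lines differ was not tested.

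Chance was examined by regrouping the libraries, fitting only the groups compared. For AML3 against AML2 the real grouping gave 2478 genes, 2861 promoters and 92 enhancers, and for each of the 3 it was 1 of 10 groupings with as many calls, the highest other giving 0. The same held, 1 of 10 with 0 as the highest other, for JQ1 in AML2 (3457 genes, 4140 promoters and 95 enhancers), JQ1 in AML3 (4425, 5181 and 212), OTX015 in AML2 (3796, 4481 and 115) and OTX015 in AML3 (5059, 5828 and 248). With 10 groupings the share cannot be under 0.1. Every other grouping mixed libraries of the 2 groups, which widens the spread where these differ, so the 0 calls there cannot settle chance. For gene lists the grouping says less. As many called lists came from 4 of 10 groupings for the lines (3 real, highest other 8), 3 of 10 for JQ1 in AML2 (13 and 17), 2 of 10 for JQ1 in AML3 (9 and 9), 3 of 10 for OTX015 in AML2 (14 and 15) and 1 of 10 for OTX015 in AML3 (9 and 8). OTX015 against JQ1 gave 0 calls, which all 10 groupings reach, with highest others of 16 genes and 3 enhancers in AML2 and 0 genes and 2 enhancers in AML3.

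For the difference between the lines, 100 of 200 groupings were drawn. As many genes were called in 8 of 100 for JQ1 (709 real, highest other 5391) and 8 of 100 for OTX015 (876 and 5946). As many enhancers were called in 9 of 100 for JQ1 (11 and 244) and 11 of 100 for OTX015 (3 and 298). By these shares chance is not excluded. Yet the other groupings as large, 7 and 7 for genes and 8 and 10 for enhancers, all left 1 line as labelled, so they hold the drug effect of that line. The highest of them gave several times the real count. It swapped drug and vehicle for all 6 libraries of AML2, so it adds the drug effects of both lines and says nothing about chance. The 75 groupings that relabelled libraries in both lines gave at most 0 genes and 0 enhancers for either compound. They mix drug and vehicle libraries in both lines, which widens the spread within groups, so these 0 calls cannot settle whether chance made the difference.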

How the results depend on the processing

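Only the refit on replicates 1 and 2 alone was chosen here after the results had been seen. Several counts changed with the setting. Genes with a different JQ1 or OTX015 effect in the lines, 696 and 767, were 1149 and 1230 with a block for the replicate number, and 1263 and 1410 with replicates 1 and 2 alone. The labels do not say what a shared number stands for. Within a line 9 of 18 same-number pairs had r over 0.1 (−0.053 to 0.623), 4 of the 6 pairs of number 3 among them, with a median of 0.105 against −0.0605 for other numbers. Of 18 libraries, 10 correlated best with their own number, so whether the numbers mark a shared culture or batch stays open. With the block the MHC class II list passed for OTX015 in AML2 (adjusted p = 0.0436). Leaving out single libraries gave 462 to 723 for JQ1. Genes that differed between OTX015 and JQ1, 0, were 1 in AML2 with DESeq2, and 4 in AML2 and 1 in AML3 with replicates 1 and 2 alone. For enhancers, library sizes from the enhancer table gave 67 for JQ1 in AML2, 173 for JQ1 in AML3, 86 for OTX015 in AML2 and 186 for OTX015 in AML3, and DESeq2 gave 71, 196, 93 and 218, with 46 for the lines. No filter on low counts gave 66 for JQ1 and 95 for OTX015 in AML2. Leaving out single libraries gave 58 to 95 for the lines, 58 to 87 for JQ1 in AML2 and 85 to 135 for OTX015 in AML2. The JQ1 effect differed at 14 enhancers with at least 5 tags, 12 with the block, 11 with only the groups compared, 12 with replicates 1 and 2 alone, 0 with no filter, 0 with DESeq2 and 0 to 10 without single libraries. The OTX015 effect differed at 19 with replicates 1 and 2 alone, 0 with no filter, 0 with DESeq2 and 0 to 4 without single libraries. OTX015 against JQ1 in AML2 gave 4 enhancers with replicates 1 and 2 alone. Called gene lists with an estimated correlation numbered 0 for the lines, 3 for JQ1 in AML2, 0 for JQ1 in AML3, 3 for OTX015 in AML2 and 0 for OTX015 in AML3, and fry called 7 for the lines and 17 for OTX015 in AML3. Without single libraries 1 to 3 lists were called for the lines. Line genes moved towards AML2 were 279 for JQ1 and 314 for OTX015 at 2-fold in each comparison, 756 for OTX015 with replicates 1 and 2 alone, and 310 to 422 for JQ1 and 330 to 458 for OTX015 without single libraries. Genes shared by the compounds in AML2 were 2036 at 2-fold. The odds ratio of lower enhancers near lower promoters for JQ1 in AML2 was 0 at 1 to 50 kb, 1.62 at 1 to 500 kb and 0 to 18.5 without single libraries. For JQ1 in AML3 it was 1.34 with the block. The difference of OTX015 from JQ1 changed sign without single libraries for BCL2 in AML2 (−0.1921 to 0.438), HOXA9 in AML2 (−0.166 to 0.0633), and in AML3 for MYC (−0.0838 to 0.2884), HEXIM1 (−0.4302 to 0.7036) and HOXA9 (−0.1752 to 0.1827), none of them called. Among 528 called results of single genes, the sign changed in 0 of 6495 refits. Many of these genes were named because their libraries did not overlap or their adjusted p was small. A change of sign was therefore unlikely from the start, and the 0 is little measure of stability. In uncalled results the sign changed in 114 of 1391 refits. With DESeq2 526 of 536 results of single genes stayed as they were and 10 lost the call. Of 3402 refits of single genes without 1 library, 3266 left the call as it was, and most others lost it. Calls of single enhancers were lost in 61 of 282. The cause of these changes was not tested.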

Other observations

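Chosen after the results had been seen were the metallothionein genes, MALAT1, its tag position, the enhancer share without the most tagged sites, and the comparison by depth with its 95% limit. MALAT1 and NEAT1, long RNAs kept in the nucleus, rose with both compounds. MALAT1 rose by 3.40 on the log2 scale with JQ1 in AML2, 4.16 with JQ1 in AML3, 3.85 with OTX015 in AML2 and 4.28 with OTX015 in AML3, and took on average 0.15% of gene tags in AML2 and 0.241% in AML3 with vehicle against 1.79% and 5.76% with JQ1. NEAT1 rose by 6.38 (SE 0.65) with OTX015 in AML3. A larger share of nuclear RNA in the drug libraries would raise other nuclear RNAs alike. The median change of 7 of them was 0.705 to 0.884, 3 or 4 rose and 0 fell, and the highest sum of median and SD was 3.108, below MALAT1 in every comparison. A tag position used only with drug would leave vehicle tags elsewhere, but at least 99.43% of MALAT1 tags lay in the same promoter with vehicle. Neither explanation accounts for the size of the rise.

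Metallothionein genes, which bind zinc and copper, fell with drug in AML3. All 6 tested were higher in AML3 than in AML2 with vehicle. In AML3 6 fell with each compound. In AML2 MT1A had 0 tags and MT1G 8 with vehicle, which leaves little or no room for a fall there, and of the other 4, MT1E and MT1F fell with each compound. For these 4 the effect was lower in AML3 with each compound. MT1F went in AML3 from 133 ± 24.6 to 5.79 ± 3.52 CPM with JQ1 (log2 −4.35, SE 0.32) and to 1.82 ± 1.67 with OTX015 (log2 −5.86, SE 0.40), and MT1E from 426 ± 165 to 14.9 ± 3.69 with JQ1 (log2 −4.78, SE 0.44). Some of the counted calls rest on single libraries. MT2A between the lines did not pass without AML3 vehicle replicate 1 (adjusted p = 0.0513), nor MT1F with OTX015 in AML2 without AML2 vehicle replicate 1 (0.116) or AML2 OTX015 replicate 1 (0.198) or 2 (0.0507). For the JQ1 difference, MT1E did not pass without AML2 JQ1 replicate 3 (0.0591) and MT2A without AML3 vehicle replicate 1 (0.0571). MT1X lost the JQ1 difference without most single libraries (up to 0.119), and the OTX015 difference without AML2 vehicle replicate 2 (0.0695), AML2 OTX015 replicate 3 (0.0678) or AML3 vehicle replicate 1 (0.0672) or 2 (0.0658). Tags of these similar genes may be split by alignment, which was not tested.

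The enhancer share was higher with both drugs in both lines. If a few abundant enhancers or promoters made the rise, it would end without them, yet without the 10 most tagged of each the lowest ratio to vehicle was 1.965. Lower depth as the whole cause would leave drug libraries of matched depth at the vehicle share. In each line 2 libraries of each compound had at least 95% of the tags of the shallowest vehicle library, and their share was at least 1.589 times the highest vehicle share with JQ1 and 1.789 times with OTX015. The shallowest vehicle library also had the lowest vehicle share. Whether depth adds to the higher share of the shallower drug libraries, those numbered 3, stays open. Tags from inside genes would not raise enhancers that overlap no gene, but the lowest median change of 309 such enhancers was 0.868 (SE 0.123). A larger share of nuclear RNA, examined above for MALAT1, was not tested for the enhancer share and stays open. The median change of the 7 nuclear RNAs in AML2 was 0.705 with JQ1 and 0.827 with OTX015. Over all tested enhancers it was 0.719 and 0.803 there. In AML3 the medians were 0.865 and 0.884 for the nuclear RNAs and 1.23 and 1.26 for the enhancers. With no spike-in named, fewer promoter tags cannot be told apart from more enhancer tags.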
